A study of Caenorhabditis elegans with 70 samples.

How the data were processed

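The series holds 70 samples of whole young adult worms grown at 21 °C, whose labels give no strain (the growth protocol names N2, and for CeHR also AB1): 6 antibodies (H3K4me3, H3K9me3, H4K20me1, H3K36me1, RNA polymerase II and H3K27me3) and a control, in 5 conditions with 2 replicates each. Per the labels, 5 µg of antibody met 300 µg of extract, and libraries were made from 5 ng of DNA. Peak files of 60 samples were used, and the 10 controls were not analysed here. The authors' notes name FastQC 0.11.2, BWA and HOMER, and the peak names carry the mark of MACS; other versions, the genome build and the use of the controls are not given in the sources used here.

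The 50 summit lists of 5 antibodies hold 1 bp summits with a deposited −log10 q, whose smallest value is near 2 (q = 0.01) in most lists, up to 2.82 in some lists of the S-Medium line, and 1.32 in the P0 lists of RNA polymerase II (q = 0.05). The 10 broad peak lists of H3K27me3 hold intervals with a deposited score, and their last 3 columns were not used, as their order of size rules out a fold, p and q. Scores were used only for ranks within a list and for a threshold common to the lists of an antibody. The broad peaks end at the chromosome lengths of WBcel235, so the RefSeq annotation of that build was used, with 19971 protein-coding genes on the 6 nuclear chromosomes. That table gives no strand, so either gene end stood in for the gene start. Read depth per library is unknown, and the precision of a list is known only from its partner replicate.

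Peak number (log2) and 4 shares of peak positions (chromosome X, the outer 0.333 of each autosome at either end as arms, within 500 bp of a gene end, and gene bodies; midpoints of broad peaks) were tested over all 5 conditions by the F ratio against all 945 partitions of 10 libraries into pairs, so that the smallest possible p is 0.00106. Replicate overlap was the Jaccard index of occupied genes within minus between conditions over the same partitions. P values were adjusted by Benjamini–Hochberg over the 6 antibodies or the 24 location tests, with a threshold of 0.05.

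Genes gained and lost were counted for P0 to F1 CeHR, P0 to F1 S-Medium, and each F1 to its reversion. They stand beside the means of the crossed pairings of the same 4 libraries and of 100 simulations. Each simulation drew the genes of each library independently, at that library's rate among genes occupied in equally many of the 10 libraries. This reference, called list length alone below, also keeps part of a difference between conditions. Persistence was tested by Fisher's exact test, adjusted over 12 tests, and joint change of H3K4me3 and RNA polymerase II by the same test, adjusted over 4. The same odds ratio for every pair of summit antibodies was added as a reference after the data were seen. Liquid against agar used Fisher's exact test per gene and 100 of the 210 splits of 10 libraries into 4 and 6. Of 38 gene lists fixed beforehand, 37 with at least 10 members were tested with limma on the log2 odds ratio of occupancy against all other genes (0.5 added to each cell). Regions of 500 kb with a mean of at least 2 peaks were tested with limma on the log2 share of peaks. Both used 8 contrasts of all 10 libraries of an antibody, adjusted over all features and contrasts. The 0.5 moves log odds when few members are expected, so only lists and regions that also passed with at least 2 expected per library are named, a filter chosen after the data were seen.

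Genes named by rank were fixed beforehand by rule, among those with a symbol of letters, hyphen and number: per antibody and medium, the 2 gained and 2 lost genes with the highest lower-replicate percentile, and per medium the 5 genes changed for most antibodies. Up to 4 moving members per list are named, and the lists and regions themselves were picked after their values were seen. Alternatives covered score threshold, list length, windows, absence, region size, replicate number and left-out libraries.

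On simulated data, the partition test passed 4% of sets without a difference and 98% of sets with one. Without change, limma called 13 of 296 lists for H3K27me3, 47 for H4K20me1 and 24 for H3K36me1, which the filter on expected members brought to 13, 0 and 5, and no lists for the other antibodies and no regions. With 6 of 37 lists changed, false calls were 5 (RNA polymerase II), 4 (H3K36me1), 3 (H4K20me1), 2 (H3K27me3) and 0 (others). Of 20 changed regions limma called 20 for H3K27me3 (and 4 others), 9 for H3K4me3 and 5 for RNA polymerase II. It called 2 for H3K36me1 and 0 for H3K9me3 and H4K20me1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.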

Results

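Peak lists were compared for 6 antibodies in whole young adult Caenorhabditis elegans of 5 conditions: the parental generation on bacteria-seeded agar (P0), its progeny in the bacteria-free liquid medium CeHR (F1 CeHR) or in liquid S-Medium with bacteria (F1 S-Medium), and the next generation of each liquid line put back on agar (CeHR reversion and S-Medium reversion). Values are means ± SD over 2 libraries (n = 2) unless given otherwise, and log2 changes from limma are given ± SE. A gene counted as occupied when a peak lay in its body or within 500 bp of it, as gained when it was occupied in both libraries of the later condition and in neither of the earlier one, and as lost in the opposite case. No label gives the strain of a sample, and the growth protocol names N2 and AB1 for CeHR but only N2 for S-Medium, so a strain difference in contrasts with the CeHR line is not excluded.

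H3K27me3, the mark of Polycomb repression, covered 5.83 ± 0.117 Mb on P0 agar, 6.68 ± 0.170 Mb in F1 CeHR, 9.39 ± 0.0188 Mb in F1 S-Medium, 8.22 ± 0.671 Mb in CeHR reversion and 11 ± 1.47 Mb in S-Medium reversion. Its peaks numbered 6408.5 ± 14.8 in P0, 6612.5 ± 43.1 in F1 CeHR, 7624.5 ± 29 in F1 S-Medium, 9085 ± 11.3 in CeHR reversion and 8140 ± 593 in S-Medium reversion, and these numbers differed among the 5 conditions (adjusted p = 0.00317, exact permutation test over 945 partitions), though not once every list was held to a common score threshold (adjusted p = 0.530). The 5 other antibodies were deposited as summits. H4K20me1, a mark tied to X-chromosome dosage compensation, gave 1923.5 ± 185 summits in P0, 3371.5 ± 57.3 in F1 CeHR, 5230 ± 652 in F1 S-Medium, 274 ± 158 in CeHR reversion and 4411.5 ± 145 in S-Medium reversion (adjusted p = 0.00317, exact permutation test). H3K36me1 gave 2651 ± 607 summits in P0, 5208.5 ± 79.9 in S-Medium reversion and 620 ± 15.6 in CeHR reversion (adjusted p = 0.00635, exact permutation test). RNA polymerase II summits numbered 2598 ± 164 in P0, 5112.5 ± 846 in F1 S-Medium and 1293 ± 48.1 in CeHR reversion (adjusted p = 0.0143, exact permutation test). Neither H3K4me3, the promoter mark, nor H3K9me3, the heterochromatin mark, passed the test on peak number (adjusted p = 0.165 and 0.102, exact permutation tests). Without the CeHR reversion lists the H3K36me1 and RNA polymerase II calls ended (adjusted p = 0.0571 and 0.114, exact permutation tests with fewer partitions), while numbers in F1 S-Medium remained 1.88 and 1.97 times those in P0. The depth of the libraries is not given in the sources used here, so the numbers of peaks carry an unknown share of sequencing depth.

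**Figure D1:**
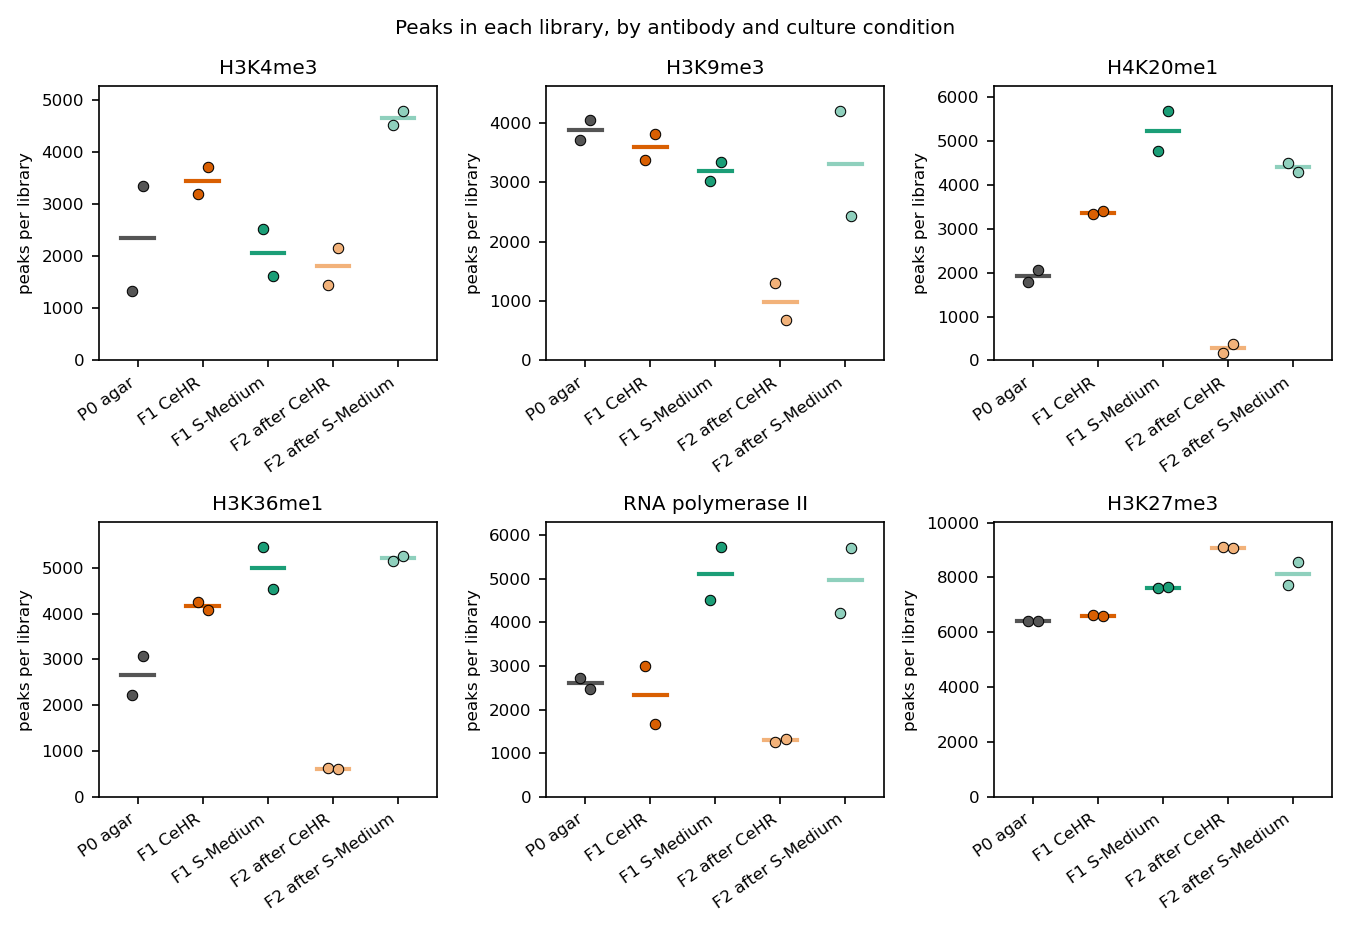
Number of peaks in each of the 10 libraries of every antibody, by condition, with points for libraries and bars for the mean. The H4K20me1 lists of CeHR reversion hold 162 and 386 summits, against 4769 and 5691 in F1 S-Medium.

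Chromosome X, 17.7% of the genome, held 20.7 ± 0.554% of H3K4me3 summits in S-Medium reversion and between 10.8% and 12.5% in the other conditions (adjusted p = 0.0416, exact permutation test). H4K20me1 also had a large mean X share in that group, 19.6 ± 5.30%, but also 17.1 ± 8.45% in CeHR reversion, on 162 and 386 summits. Its 5 conditions did not pass the same test (adjusted p = 0.365, exact permutation test), while the 4 without CeHR reversion did (adjusted p = 0.0381, exact permutation test). The X share of RNA polymerase II summits ran from 9.53% in S-Medium reversion to 12.4% in F1 CeHR, and that of H3K27me3 peaks from 10.8% in S-Medium reversion to 12.1% in P0 (adjusted p = 0.00847 for each, exact permutation tests). H3K36me1 differed too, between 9.26% and 13.8% (adjusted p = 0.0102, exact permutation test). The X shares of RNA polymerase II and H3K36me1 no longer differed at equal list length (adjusted p = 0.599 and 0.897, exact permutation tests). For H3K4me3 the call ended without CeHR reversion (0.0623), under a common score threshold (0.0818), with the replicate number as a block (0.109) and with the higher-scoring peaks alone (adjusted p = 0.227, exact permutation tests) and for H3K27me3 as well (adjusted p = 0.120, same exact test). H3K27me3 peaks lay within 500 bp of a gene end in 17% of cases in P0, 15.5% in F1 CeHR, 21.3% in F1 S-Medium, 19.9% in CeHR reversion and 22% in S-Medium reversion (adjusted p = 0.00847, exact permutation test), a call that ended under a common score threshold (adjusted p = 0.0818). Of the 24 tests on location, 11 passed, and every group mean of the share within 500 bp of a gene end was below the 31.1% of the genome that such positions make up. That includes H3K4me3 (10.7% in P0 to 13.3% in S-Medium reversion) and RNA polymerase II (9.97% in CeHR reversion to 16.7% in S-Medium reversion). H4K20me1 in P0 had 11.1% of its summits on X, below the 17.7% of the genome. Whether the summit lists report the named marks was not tested, so changes given below are changes of these lists.

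**Figure D2:**
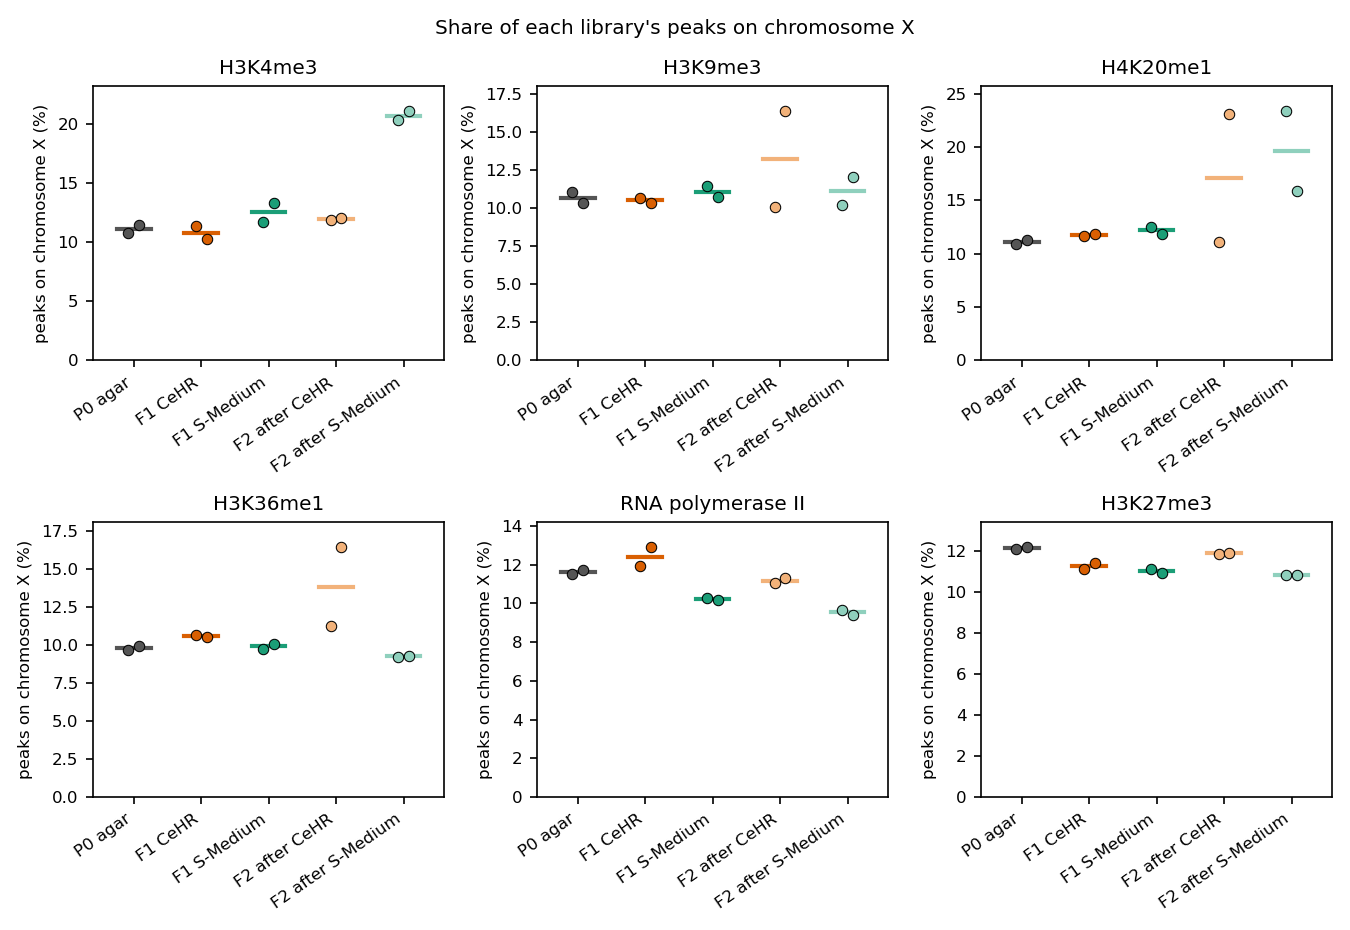
Share of each library's peaks on chromosome X in percent, by antibody and condition, with points for libraries and bars for the mean. Both H3K4me3 libraries of S-Medium reversion lie above the 17.7% of the genome that X makes up.

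The genes occupied in the 2 replicates of a condition overlapped more, on average, than those of different conditions for every antibody. The Jaccard index was 0.773 within and 0.590 between conditions for H3K27me3, 0.612 and 0.285 for H4K20me1, 0.677 and 0.366 for H3K36me1, and 0.580 and 0.376 for H3K9me3 (adjusted p = 0.00317 each, one-sided exact permutation tests). It was 0.644 and 0.408 for RNA polymerase II (adjusted p = 0.00762) and 0.541 and 0.427 for H3K4me3 (adjusted p = 0.0265), in the same exact permutation tests. The H3K4me3 call ended with the replicate number as a block (adjusted p = 0.0667) and without CeHR reversion (0.0571), in exact permutation tests. That of RNA polymerase II ended at equal list length (0.0519) and without CeHR reversion (0.0571), in exact permutation tests. The 2 H3K4me3 libraries of P0 overlapped at 0.245, less than P0 and F1 CeHR did on average (0.469). Summit lists of different antibodies also resembled each other: outside CeHR reversion, a median of 68.9% of a list's summits lay within 250 bp of a summit of at least 3 of the 4 other summit antibodies, in the same condition. Across antibodies the index was 0.474 in the same condition and 0.358 in different ones. For the same antibody in different conditions it was 0.372. Lists of different antibodies from 1 condition were thus more alike than lists of 1 antibody from different conditions. Gained and lost genes of the 5 summit antibodies are therefore given, for most contrasts, beside simulations from pooled sites, called list length alone. The simulations keep each library's rate among genes found in equally many libraries, and so also part of a difference between conditions. A count near theirs does not show that only list length differed.

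In F1 CeHR, H3K27me3 was no longer found over the nspc genes, a family of small nematode-specific peptides on X. They were occupied at 77.8 ± 7.86% in P0 and at 0% in both F1 CeHR libraries, and 13 of the 18, among them nspc-1, nspc-2, nspc-4 and nspc-5, met the definition of lost. The major sperm protein (msp) genes were occupied at 51.6 ± 18.2% in P0 and 16.1 ± 4.56% in F1 CeHR, where msp-51, msp-79, msp-45 and msp-31 were lost. The list of sperm genes, which holds both families, fell from 38.2 ± 5.35% to 15.5 ± 1.78%, by −1.75 ± 0.31 (SE) in log2 odds against all other genes (limma adjusted p = 0.00160), and still fell with the nspc genes left out (−1.02 ± 0.31, adjusted p = 0.0262). Cuticle collagens fell from 15.2 ± 1.65% to 7.60% in both libraries (−1.12 ± 0.20, adjusted p = 0.00155), with col-167, col-157, col-169 and col-166 among 7 lost and col-186 and col-54 gained. Histone genes fell from 10.4 ± 6.87% to 2.08 ± 0.982% (−2.04 ± 0.45, adjusted p = 0.00471), though no single histone gene met the definition of lost.

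A list written for osmotic stress also passed in this contrast (−2.67 ± 0.20), but its moving members were the nspc genes, and without them its change was −0.02 ± 0.27 (adjusted p = 0.966). The nspc, msp and histone genes are multi-copy families of near-identical sequence. They lie in 3, 11 and 17 clusters, so that a few peaks can hold many of the genes counted. The breakdown by family was chosen after the values were seen. H3K27me3 rose over the 12 dosage compensation genes, from 16.7% to 33.3% in both libraries of each group (1.14 ± 0.22, adjusted p = 0.00264), where sdc-1 was gained, and over regulators of hypoxia, oxidative and xenobiotic stress, from 9.76 ± 3.45% to 17.1% (0.88 ± 0.21, adjusted p = 0.00710), where the peroxiredoxin gene prdx-6 and the catalase gene ctl-1 were gained. Both of these ended when only gene ends were counted, where the dosage compensation change was close to none, with its sign turned. Proteasome genes rose from 8.77% to 14% (0.70 ± 0.17, adjusted p = 0.00797) and oxidative phosphorylation genes from 8.09 ± 1.04% to 12.5 ± 1.04% (0.64 ± 0.22, adjusted p = 0.0429). Both ended at equal list length, and the histone and stress-regulator calls ended under a common score threshold. In simulated data without change, limma called 13 of 296 H3K27me3 lists, against 99 here. Every call named here for F1 CeHR ended when only the higher-scoring peaks of each list were kept, where the collagens stood at 0.10.

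Among single genes, H3K27me3 was gained in F1 CeHR within 500 bp of the F-box gene fbxa-75 and of efhc-1. The peak beside fbxa-75, at 1299619–1303247 of chromosome III, scored above 99.7% of that library's peaks. That beside efhc-1, at 10360952–10370242 of X, scored above 99.4%. A P0 library already had a peak within 2000 bp of each gene. H3K27me3 was lost over anc-1, where P0 replicate 2 had a peak at 4341102–4357413 of chromosome I. In all, 384 genes gained and 362 lost H3K27me3. On average 84 genes changed when the same 4 libraries were paired across conditions, and the simulations gave 138 and 179. At equal list length the counts were 361 and 377. Of 500 kb regions, 25 passed; chromosome IV at 9500001–10000000 fell from 24 to 16.5 peaks (−0.57 ± 0.10, adjusted p = 0.00338) and X at 6000001–6500000, where col-167 and col-169 lie, from 10.5 to 5.0 (−1.06 ± 0.18, adjusted p = 0.00371). The X region stood at 0.32 among the higher-scoring peaks alone, and both regions were chosen for naming after the values were seen.

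**Figure D3:**
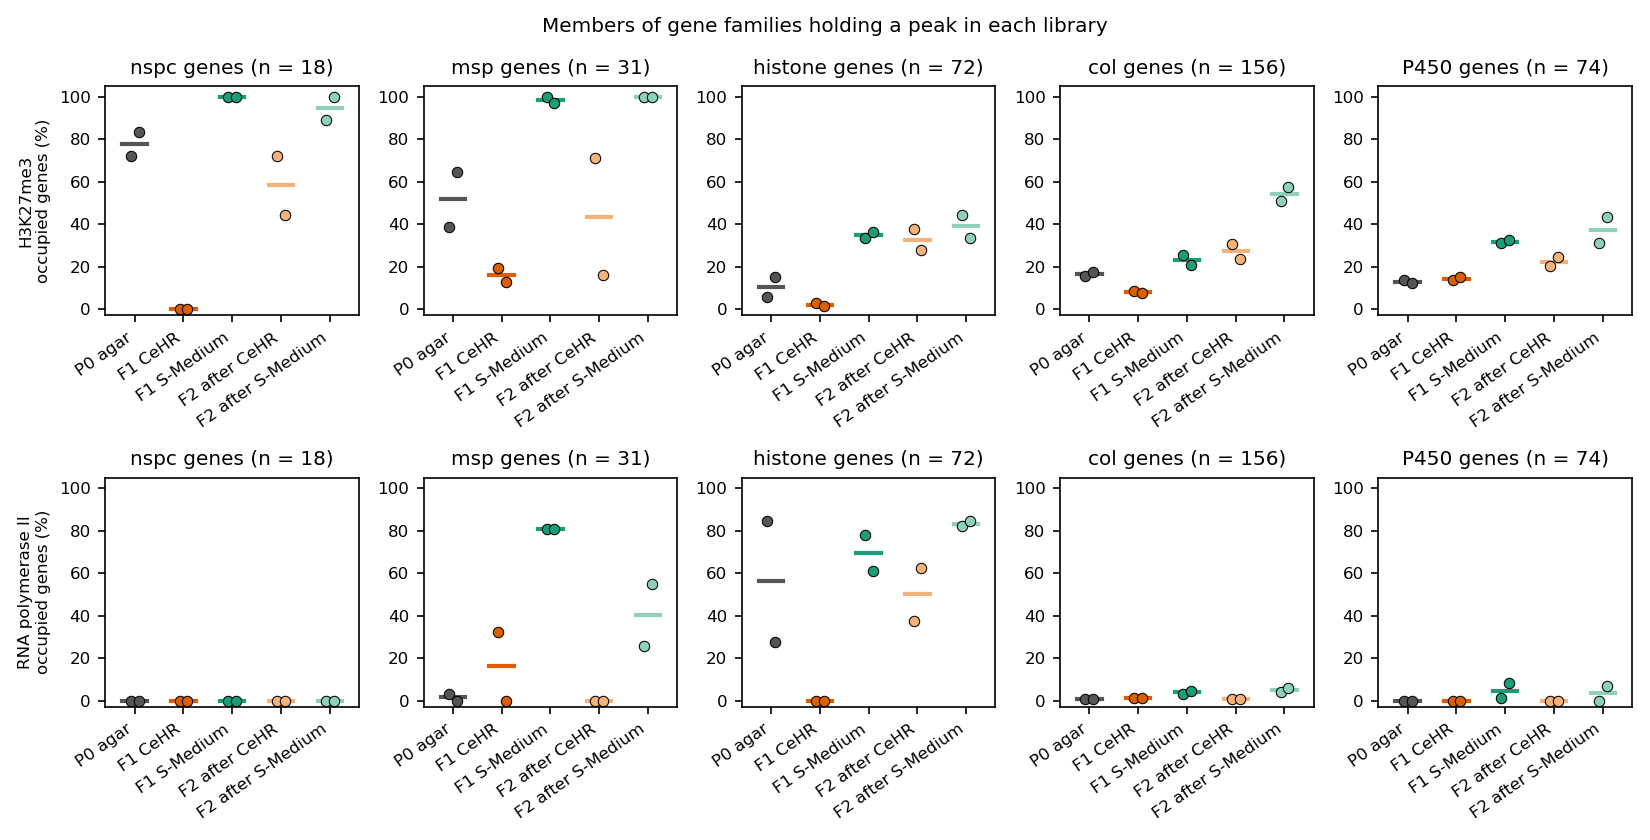
Percent of genes occupied by H3K27me3 (top) and by RNA polymerase II (bottom) in each library, by condition, for families named in the text. For H3K27me3 the nspc genes stand at 0% in both F1 CeHR libraries and at 100% in both F1 S-Medium libraries.

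For the summit antibodies, RNA polymerase II was no longer found over histone genes in F1 CeHR. It occupied 56.2 ± 40.3% of them in P0 and none in either F1 CeHR library, a fall of −7.51 ± 1.12 in log2 odds (limma adjusted p = 0.0116) that was not past the threshold at equal list length (adjusted p = 0.259). The lost genes were led by his-66 and his-65, with a summit at 11400595 of chromosome IV, and his-58 and his-57. The region of IV at 11000001–11500000 fell from 21.5 to 8.0 RNA polymerase II summits (−1.26 ± 0.20, adjusted p = 0.00751). That call ended at equal list length (−1.16, adjusted p = 0.302) and without CeHR reversion (adjusted p = 0.212). H3K9me3 was lost at ttr-57, a transthyretin-like gene with a summit at 20605990 of V, and at egl-10, and gained at nlr-1 and srx-68. Over all genes H3K9me3 was gained at 217 and lost at 391, against 20 when crossed and 53.2 and 129 by list length alone. The excess of losses turned at equal list length (60 and 46) and grew with antibody-specific summits (100 and 609). H4K20me1 was gained at 464 genes and lost at 26, where list length alone gave 412 and 3.12, and antibody-specific summits 78 and 80. Its top genes were fbxa-36 and srx-68 (gained) and egl-10 and fbxa-63 (lost). Ion channel genes rose in H4K20me1 from 0.301 ± 0.426% to 5.42% (2.62 ± 0.42, adjusted p = 0.00522), where kqt-3, inx-19, lgc-54 and twk-2 were among 7 gained, but not when only gene ends or only antibody-specific summits were counted. H3K36me1 was gained at 371 genes and lost at 21 (302 and 6.39 by list length alone). At equal list length, which brings the 2 counts towards balance, these were 58 and 50. The gains were led by mvk-1 and the nuclear receptor gene nhr-104, and the losses by sra-12 and hrpu-1. H3K36me1 rose over the region of V at 13500001–14000000 from 1.5 to 8.0 summits (1.46 ± 0.16, limma adjusted p = 0.000943). RNA polymerase II (28 gained, 48 lost, with cdh-1 and dmd-9 the top gains) and H3K4me3 (69 gained, 6 lost) changed at fewer genes than when crossed (88 and 99.5). For RNA polymerase II this turned with antibody-specific summits (52 gained, 231 lost, 29 when crossed), at equal list length (23, 22 and 33) and with gene ends only (13, 37 and 34.5). It held among the higher-scoring peaks, under a common score threshold and with 1000 bp around genes. The H3K4me3 count rested on the P0 pair, with 1341 and 3351 summits: it was 878 without P0 replicate 2. Its top genes were asp-19 and srx-68 (gained) and gldi-1 and the polyubiquitin gene ubq-1 (lost).

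In F1 S-Medium, H3K27me3 was found at 100% of the nspc genes and 98.4 ± 2.28% of the msp genes. The sperm list as a whole did not pass against P0 (0.81 ± 0.31, limma adjusted p = 0.0693, and 0.86 ± 0.31 without the nspc genes, adjusted p = 0.0569). Histone genes rose from 10.4 ± 6.87% to 34.7 ± 1.96% (1.68 ± 0.45, limma adjusted p = 0.0129), and 17 were gained, led by his-51, his-52, his-21 and his-22. Cytochrome P450 genes, which encode detoxification enzymes, rose from 12.8 ± 0.956% to 31.8 ± 0.956% (1.02 ± 0.19, adjusted p = 0.00182), and 9 were gained, led by cyp-33C11, cyp-25A6, cyp-33C5 and cyp-25A4. Chemosensory receptor genes rose from 20.5 ± 1.5% to 36.5 ± 0.362% (0.60 ± 0.16, adjusted p = 0.0137), with srw-63, srx-48, sra-27 and srg-46 leading 125 gained genes. F-box genes rose from 31.7 ± 0.492% to 50.3 ± 0.984% (0.54 ± 0.14, adjusted p = 0.0127), with fbxa-75, fbxa-74, fbxa-32 and fbxa-209 leading 58 gained. Immune effectors rose from 20.6 ± 0.422% to 36.1 ± 1.27% (0.53 ± 0.16, adjusted p = 0.0202), with clec-225, clec-41, clec-227 and clec-13 leading 29 gained.

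Those last 3 calls ended at equal list length (adjusted p = 0.255, 0.114 and 0.241), where the P450 and histone calls held. The histone call ended when only gene ends were counted, and all 5 of these calls ended under a common score threshold. Housekeeping lists fell relative to all other genes because their occupied share stayed level or dropped while that of other genes grew. Heat shock proteins went from 13.9 ± 1.16% to 11.5% (−0.90 ± 0.18, adjusted p = 0.00253), and proteasome genes from 8.77% to 7.02% (−0.92 ± 0.17, adjusted p = 0.00181). Vitamin B12, methionine and propionate genes went from 22.9% to 18.8% (−0.94 ± 0.19, adjusted p = 0.00264), oxidative phosphorylation genes from 8.09% to 6.62% (−0.89 ± 0.22, adjusted p = 0.00866), and cytosolic ribosomal protein genes stood at 2.67% in both groups (−0.60 ± 0.15, adjusted p = 0.00919). Lost members were few: cct-3 of the heat shock list, ubc-14 of the proteasome list, and ndub-8, ndua-7 and cox-10 of the oxidative phosphorylation list, which also gained cox-14 and sdha-1. Of the list calls named here for F1 S-Medium, only the histones held among the higher-scoring peaks alone.

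Single genes with the highest-scoring gained H3K27me3 peaks in F1 S-Medium were again fbxa-75 and efhc-1, above 99.6% of their libraries' peaks. The losses were led by mac-1 on II and the Notch-ligand-like gene dsl-6 on IV. The peaks of fbxa-75, efhc-1 and dsl-6 lay within 500 bp outside the gene. For these genes and mac-1, a library of the condition counted as empty had a peak within 2000 bp. H3K27me3 was gained at 1060 genes and lost at 150, against 82.5 when crossed, 664 and 18.2 by list length alone, and 702 and 234 at equal length. Of 27 regions past the test, V at 17000001–17500000 rose from 47 to 94.5 peaks (0.76 ± 0.11, adjusted p = 0.00179) and the first 500 kb of X fell from 78 to 61 (−0.60 ± 0.10, adjusted p = 0.00293). The region of V stood at −0.26 among the higher-scoring peaks. The P0 lists of H3K27me3 carry a marking in their peak names that reads as a lowered significance setting, a limit on each contrast with P0.

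In F1 S-Medium, the rise at sperm genes passed for 2 summit antibodies. H4K20me1 was found at 32.8 ± 13.1% of them against 1.26% in P0 (3.06 ± 0.61, limma adjusted p = 0.0127, and 2.59 ± 0.61 without the nspc genes, adjusted p = 0.0210), with spe-41, spe-19, nspd-8 and msp-51 among 20 gained. H3K36me1 rose at the same list from 1.26% to 18.5 ± 5.94% (2.59 ± 0.35, adjusted p = 0.00130), with spe-41, msp-58, msp-65 and msp-59 among 15 gained. RNA polymerase II occupied 80.6% of the msp genes in both F1 S-Medium libraries and 1.61 ± 2.28% in P0, yet the sperm list did not pass (2.56 ± 0.72, adjusted p = 0.0656). The H3K36me1 call ended at equal list length, and a shortest list of 162 summits leaves H4K20me1 lists without a usable comparison at equal length. Ion channel genes rose in H4K20me1 to 11.4% (2.86 ± 0.42, adjusted p = 0.00377), with lgc-54, inx-19, kqt-3 and twk-2 again among the 13 gained, and stood at −0.35 when only gene ends were counted.

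H3K9me3 was gained at 222 genes and lost at 320 (28.5 when crossed, 65.5 and 114 by list length alone), but at 97 and 70 at equal list length and 78 and 644 with antibody-specific summits, with str-52 and pcdr-1 leading the gains and ttr-57 and slc-17.6 the losses. H4K20me1 was gained at 1020 genes, with fbxa-36 and srbc-20 leading, and lost at 35, with fbxa-63 and sra-12 leading, where list length alone gave 935 and 0.840. H3K36me1 was gained at 841 genes, with pes-10 and asp-19 leading, and lost at 73, among them mac-1 and daf-28 (673 and 2.39 by list length alone). It rose over V at 13500001–14000000 from 1.5 to 14.5 summits (2.01 ± 0.16, adjusted p = 0.000203) and over IV at 5000001–5500000 from 4.5 to 29 (1.70 ± 0.23, adjusted p = 0.00250). RNA polymerase II was gained at 646 genes, with rad-8 and ndx-8 leading, and lost at 7, among them srh-297 and glb-7. The simulations, which keep part of a difference between conditions, gave 694 and 0.450. At equal list length H3K36me1 was gained at 91 and lost at 86, and RNA polymerase II at 21 and 18, so the excess of gains was gone. H3K4me3 was gained at 95 genes, led by str-52 and the purine synthesis gene pfas-1, and lost at 43, led by puf-11 and mtcu-1, fewer in all than when crossed (153.5) but more than by list length alone (18.9 and 22.2). Of the 48 genes named by rank for both media, 21 had no peak within 2000 bp in the condition of absence, and 12 of the 40 named for summit antibodies held with antibody-specific summits alone.

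**Figure D4:**
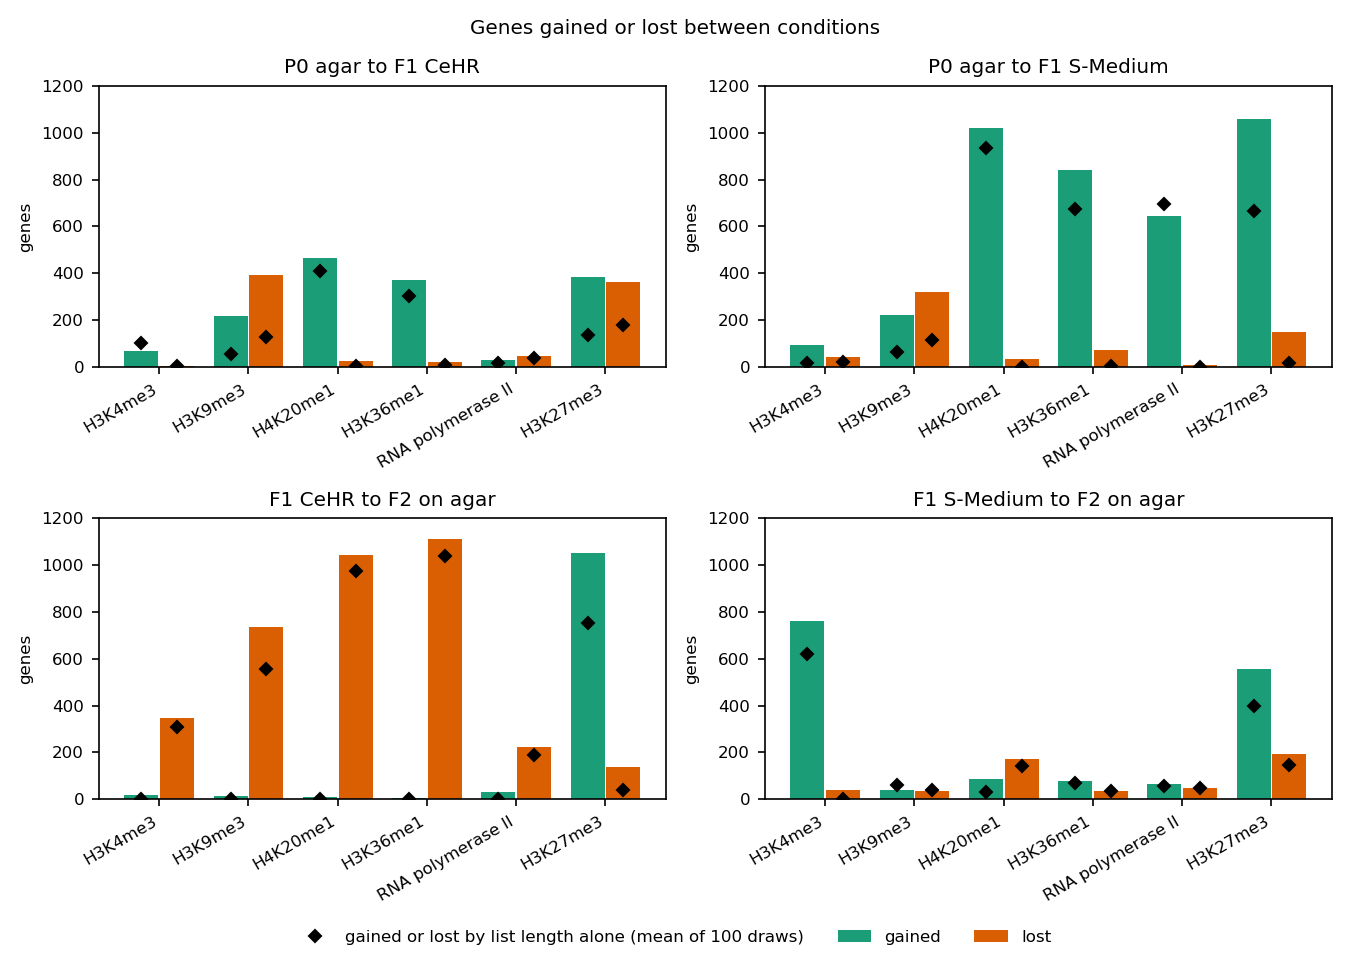
Genes gained and lost per antibody and contrast, beside simulation means (list length alone), which keep part of a difference between conditions. H3K27me3 and H3K9me3 exceed the simulation means for gained and for lost genes in the 2 contrasts with P0.

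The same genes changed in both media more often than in any of 100 simulations for H3K9me3, H3K27me3 and H4K20me1 in both directions, and for H3K36me1 in losses. H3K9me3 was lost in both at 226 genes (43.8 expected for independent sets, 90.9 on average in simulations from pooled sites) and gained in both at 38 (at most 26 in simulations). H3K27me3 was gained in both at 160 genes (at most 95) and lost in both at 17 (at most 16). H4K20me1 was gained in both at 375 (at most 369) and lost in both at 18 (at most 6), and H3K36me1 at 277 (at most 279) and 13 (at most 9). Gains in both stood at 22 (at most 23) for RNA polymerase II and 4 (at most 11) for H3K4me3. Both media were set against the same P0 libraries, which adds to the overlap. For a single antibody, 1395 genes changed in F1 CeHR and 1960 in F1 S-Medium. For 4 antibodies 17 and 74 did, and for 5 antibodies 1 and 6. Among those with a gene-class symbol, sun-1 and aos-1 gained H3K4me3, H3K9me3, H4K20me1 and H3K36me1 in F1 CeHR. In F1 S-Medium, crtc-1 and tag-273 gained all 5 summit antibodies. There fbxb-106 gained 4 of them and lost H3K9me3. Genes that gained H3K4me3 in F1 S-Medium gained RNA polymerase II at 25 loci, with an odds ratio of 19.9 against other genes (adjusted p = 5.09e-21, Fisher's exact test across genes, which are not independent). The 10 pairs of summit antibodies gave odds ratios from 15.7 to 320 in the same contrast, and this pair ranked 8, so the joint gain was no greater than for most other pairs. These tests took the 18267 genes that could have gained both. In F1 CeHR, 46 of these genes gained only H3K4me3, 11 gained only RNA polymerase II and none gained both. There the odds ratio was 127 among the higher-scoring peaks (adjusted p = 0.0195) and 42.6 with 1000 bp around genes (adjusted p = 0.00280), in Fisher's exact test.

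Set directly against each other, F1 CeHR and F1 S-Medium differed in H3K27me3 at histone genes, with 2.08 ± 0.982% and 34.7 ± 1.96% occupied (−3.72 ± 0.45, limma adjusted p = 0.000124), and at sperm genes, with 15.5 ± 1.78% and 62.2 ± 2.38% (−2.56 ± 0.31). Both held among the higher-scoring peaks alone and at equal list length. Collagens were lower in CeHR (7.60% and 21.3 ± 3.72%, −1.10 ± 0.20), and oxidative phosphorylation (12.5% and 6.62%, 1.53 ± 0.22) and proteasome genes (14% and 7.02%, 1.61 ± 0.17) were higher, with all 3 kept at equal list length but not among the higher-scoring peaks. In all 23 of the 37 lists and 55 regions differed, led by V at 17000001–17500000 with 35 and 94.5 peaks (−1.21 ± 0.11) and I at 12000001–12500000 with 32.0 and 68 (−0.87 ± 0.10). The direction of the region of V turned among the higher-scoring peaks alone.

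After return to agar from CeHR, H3K27me3 rose over histone genes and collagens. Histone genes rose from 2.08 ± 0.982% to 32.6 ± 6.87% (3.53 ± 0.45, limma adjusted p = 0.000170), with his-15, his-14, his-11 and his-10 leading 11 gained, and this call held at equal list length and among the higher-scoring peaks. Collagens rose from 7.60% to 25.1 ± 4.14% (1.36 ± 0.20, adjusted p = 0.000426), with col-48, col-167, col-168 and col-170 leading 18 gained, and not among the higher-scoring peaks. The nspc genes stood at 58.3 ± 19.6% (6 gained, among them nspc-12, nspc-15 and nspc-13) and the msp genes at 71% and 16.1% in the 2 libraries (2 gained). The sperm list rose (1.13 ± 0.31, adjusted p = 0.0155) but not with the nspc genes left out (0.63 ± 0.31, adjusted p = 0.151). The region of X at 6000001–6500000 went back from 5.0 to 15 peaks (1.05 ± 0.18), though it stood at −0.46 among the higher-scoring peaks, with adjusted p = 0.0285 in limma. Over all genes 1051 gained and 137 lost H3K27me3 (81.5 when crossed, 752 and 37.5 by list length alone), falling to 599 and 138 under a common score threshold and to 308 and 233 at equal list length.

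In CeHR reversion, losses of 4 marks were mostly of the size that the simulations gave, though each was above the highest of 100 simulations. Part of a real loss is kept in the simulations as well. H4K20me1 was lost at 1043 genes (977 on average and at most 1005 by list length alone), H3K36me1 at 1113 (1041, at most 1075), H3K9me3 at 736 (558, at most 604) and H3K4me3 at 349 (309, at most 338). With antibody-specific summits alone H3K4me3 turned, from 17 gained and 349 lost to 372 gained and 54 lost. Chemosensory receptors, with srt-50, str-81, str-264 and srh-291 leading 55 lost, and F-box genes, with fbxa-208, fbxa-190, fbxb-66 and math-34 leading 38, fell in H3K36me1 (limma adjusted p = 0.00650 for each, F-box genes by −1.66 ± 0.31), though not when only gene ends were counted. H4K20me1 fell over chemosensory receptors as well (−1.40 ± 0.34, adjusted p = 0.0232, with str-222, srt-50, srh-132 and srx-68 leading 45 lost) but stood at 0.61 when only gene ends were counted. The region of II at 12000001–12500000 fell from 23 to 0.5 H3K9me3 summits (−2.82 ± 0.31, adjusted p = 0.0176). It ended among the higher-scoring peaks (adjusted p = 0.0939), and no H3K9me3 region passed in limma at equal list length or with regions of 250 or 1000 kb (218 had an unadjusted p under 0.05 in the main analysis). RNA polymerase II was lost at 224 genes and gained at 32 (190 and 0.590 by list length alone), but gained at 268 and lost at 78 with antibody-specific summits. The histone-bearing region of IV at 11000001–11500000 went back from 8.0 to 16.5 summits (1.89 ± 0.20, adjusted p = 0.00117), a call that ended at equal list length (1.77, adjusted p = 0.164).

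After return to agar from S-Medium, the collagens carried the largest H3K27me3 change. They rose from 21.3 ± 3.72% to 51.2 ± 4.55% (1.75 ± 0.20, limma adjusted p = 8.32e-05), with col-126, col-127, col-180 and col-10 leading 34 gained, and held at equal list length and among the higher-scoring peaks. Muscle genes rose from 24.5 ± 2.89% to 43.9 ± 1.44% (1.04 ± 0.19, adjusted p = 0.00160), with unc-78, unc-22, the myosin gene myo-3 and unc-89 among 7 gained. Hypodermis genes rose from 20.9 ± 1.23% to 33.5 ± 1.84% (0.72 ± 0.16, adjusted p = 0.00450), led by grl-30, nas-2, mlt-11 and grd-3, and intestine genes from 22.5% to 33.8 ± 5.30% (0.59 ± 0.16, adjusted p = 0.0160), led by asp-18, ifd-1, cpr-5 and asp-1. These 3 calls ended at equal list length and under a common score threshold. Among the higher-scoring peaks the hypodermis change was close to none, with its sign turned. Of 7 regions past the test, II at 2500001–3000000 rose from 60.5 to 90.5 peaks (0.49 ± 0.11, adjusted p = 0.0143) and II at 3000001–3500000 from 63.0 to 92.0 (0.45 ± 0.10, adjusted p = 0.0143). H3K27me3 was gained at 556 genes and lost at 195 (154 when crossed, 399 and 145 by list length alone), but under a common score threshold 194 of the 306 changed genes were lost (243 changed when crossed). H3K4me3 was gained at 763 and lost at 38 (623 and 1.74), but at equal list length at 76 and 94. Of the 763, 10 were nspc genes, with none of that family occupied in another condition. H3K9me3 (38 and 37), H3K36me1 (78 and 37) and RNA polymerase II (64 and 47) changed at no more genes than when crossed or hardly more (127.5, 114 and 187.5), and H4K20me1 was gained at 87 and lost at 174 (30 and 144 by list length alone).

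For H3K27me3, H3K36me1, H3K9me3 and H4K20me1, genes gained in F1 S-Medium were occupied after reversion more often than genes lost. Both S-Medium reversion libraries occupied 70.3% of the genes gained and 10.7% of those lost for H3K27me3 (adjusted p = 6.50e-45), 86.4% and 8.22% for H3K36me1 (3.06e-44), 50% and 5.00% for H3K9me3 (1.75e-34) and 66.9% and 8.57% for H4K20me1 (6.83e-12), all by Fisher's exact test across genes, which are not independent. Neighbouring genes can share a peak, and a gene missed only in the P0 lists would count as gained and then as occupied. With antibody-specific summits alone the H4K20me1 difference was 1.96 percentage points and no longer passed (adjusted p = 0.807, Fisher's exact test). RNA polymerase II (65.5% and 28.6%, adjusted p = 0.0811) and H3K4me3 (46.3% and 60.5%, adjusted p = 0.191) did not pass that exact test. Under other settings they did. RNA polymerase II passed at equal list length (61.1 percentage points, adjusted p = 0.000383), with 1000 bp around genes (66.7, 4.50e-05) and with antibody-specific summits (17, 1.70e-08). H3K4me3 passed with fewer gained than lost genes occupied, as in its main value, at equal list length (−25.6, 0.00166) and among the higher-scoring peaks (−36.5, 0.00295), all by Fisher's exact test. It turned with gene ends only (19 points), without passing (adjusted p = 0.467, same exact test). In the CeHR line, H3K27me3 was found in both reversion libraries at 69.3% of genes gained and 68% of genes lost in F1 CeHR (adjusted p = 0.870, Fisher's exact test), and other settings went both ways. The difference was 12.1 points at equal list length (adjusted p = 0.00166), −6.86 among the higher-scoring peaks (0.356) and −8.43 with gene ends only (0.0613), in the same exact test. For H4K20me1 these shares were 0% and 7.69% (adjusted p = 0.00543), for H3K36me1 0.539% and 9.52% (adjusted p = 0.0264) and for RNA polymerase II 0% and 31.2% (adjusted p = 0.00141), by the same exact test on lists that were short in that group. With antibody-specific summits RNA polymerase II turned to 18.4 points (adjusted p = 0.0153), and its call ended among the higher-scoring peaks (adjusted p = 1), in Fisher's exact tests. The H4K20me1 and H3K36me1 calls ended with gene ends only (adjusted p = 1 for each, same exact test), and that of H4K20me1 also on the 162 summits of equal list length (0.203). H3K9me3 (2.30% and 2.81%, adjusted p = 0.870) and H3K4me3 (4.35% and 0%, adjusted p = 1) did not pass the exact test, though H3K4me3 turned and passed with 1000 bp around genes (−24.5 points, adjusted p = 0.00529).

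No gene separated the 4 liquid libraries from the 6 agar libraries after adjustment for any antibody in Fisher's exact test. With only 210 possible splits its p has a floor, and few genes if any were able to pass the adjustment. At an unadjusted p under 0.05 the test gave 58 genes for H3K27me3, 66 for H4K20me1, 33 for H3K9me3, 28 for H3K36me1, 4 for RNA polymerase II and 1 for H3K4me3, and between 15 (H4K20me1) and 98 (H3K4me3) of 100 splits of the same libraries gave as many.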

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

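The tests of transcribed chromatin, of a common extract and of single-library depth, and the reference for mixed chromatin, were chosen after seeing the data; the other tests in this part were written before. The contrast of F1 CeHR and F1 S-Medium itself passed in limma for 23 lists in H3K27me3, 4 in H4K20me1, 2 in RNA polymerase II and 1 in H3K36me1. It also passed for 55 regions in H3K27me3, 6 in H3K36me1 and 2 in RNA polymerase II. Histone genes (−3.72), oxidative phosphorylation genes (1.53) and proteasome genes (1.61) in H3K27me3 passed in opposite directions in the 2 media. Collagens in H4K20me1 (−1.83) did so only without the filter on expected members. Their difference rests on 0.585% and 5.26% of members occupied, and stood at 0.02 at equal list length. Groups of 2 libraries are too small to test for a single library far from the others.

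Summit lists of different antibodies shared most of their sites, a median of 68.9% outside CeHR reversion and 11.5% in it, although H3K4me3, H3K9me3 and H3K36me1 mark different chromatin. Weak background near the calling threshold would put the shared sites among the weaker summits, but they made up 23.4 percentage points more of the stronger part of a list (lower quartile 11.2), which speaks against it. Transcribed open chromatin would put them in or near genes, but in 49 of 50 lists they lay there less often than the genome average. Repeats or other features of the arms were to put shared sites more on arms and less near genes than the other summits, in most lists. That held in 10 of 50. However, shared sites lay on arms in a median of 74.4% and the other summits in 71.4% (genome 54.9%). In or near genes lay 56.0% and 55.4% (genome 73.8%). A cause acting on both kinds of summit would not show in this comparison, so it cannot tell. The tests leave sites recovered by any antibody as a possible technical cause, and none of them separates such sites from shared biology.

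The X share of H3K4me3 and H4K20me1 summits was large in S-Medium reversion, 20.7 ± 0.554% and 19.6 ± 5.30% (23.4% and 15.9% in the 2 H4K20me1 libraries). For H4K20me1 it was also 23.1% in replicate 2 of CeHR reversion (386 summits) and 11.1% in replicate 1 (162). Without CeHR reversion its share differed among conditions (adjusted p = 0.0381, exact permutation test), and with it the test did not pass (0.365). A common extract or control would raise it for the other antibodies as well, but the highest of their gaps to the other conditions was −2.13 percentage points, against that cause. A few X regions did not account for it, with at most 16.5% of X summits in the 3 fullest regions (lowest 15.4%). Mixed material or an antibody mix-up would put H3K4me3 summits of X near H4K20me1 summits at least as often as those of autosomes; the difference was −27.8 percentage points at its lowest and −10.6 at its highest. Replicates of the same antibody, which hold 1 kind of chromatin, also gave −1.95 to −31.2 points, so that test cannot tell.

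The summit lists of CeHR reversion were the shortest for H3K9me3, H4K20me1, H3K36me1 and RNA polymerase II, though peak number did not pass for H3K9me3. Those of H3K4me3 (1458 and 2166) lay within the range of P0. H4K20me1 had 274 ± 158 summits against 3371.5 ± 57.3 in F1 CeHR. A weak common extract would also shorten the H3K27me3 lists, which were 1.12 times the highest mean of the other conditions. These lists reached down to lower scores (180 and 342), but at a common score threshold the ratio was 1.12 as well (7285 and 8161 peaks in CeHR reversion, 5299 to 7430 in the other libraries), against that cause. This holds as far as scores of different lists compare, and these lists came from another kind of peak calling. Lower depth or enrichment of single libraries would leave mainly the usual sites: 80.4% of H3K9me3 summits, 74.8% of H3K36me1 and 69.3% of H4K20me1 lay near a summit of the same antibody in another condition, which cannot tell low depth from a real loss.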

How the results depend on the processing

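The alternatives for score threshold, list length, window, arms, absence, merging of summits, region size, replicate number and left-out libraries were written before the data were examined, and without the CeHR reversion libraries, with antibody-specific summits, with at least 2 expected per library and with the nspc genes left out are tests chosen after seeing the data. Apart from left-out libraries, 410 of the values for the comparisons stayed, 170 counts moved by over 1.5 times, 40 ended, 19 came to pass and 11 reversed. Merging summits changed no call on peak number and does not apply to broad peaks, the replicate number was not used for counts of changed genes, and antibody-specific summits do not exist for H3K27me3. The lists of H4K20me1 at equal length rest on 162 summits per library and are of no use. For the changes listed in this part the cause was not tested, unless stated.

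Peak number, as adjusted p of exact permutation tests. Without the CeHR reversion libraries it was 0.0571 for H3K36me1 and 0.114 for RNA polymerase II. It was 0.530 for H3K27me3 with a common score threshold.

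Peak location, as adjusted p of exact permutation tests. Location with only peaks scoring above their list's median gave 0.227 for H3K4me3 on X, 0.0439 for H3K9me3 in gene bodies, 0.0317 for H4K20me1 on arms, 0.655 for H3K36me1 on X, 0.0254 for H3K36me1 on arms, 0.0381 for H3K36me1 in gene bodies, 0.120 for H3K27me3 on X. It gave 0.0254 for H3K27me3 on arms. Location with a common score threshold gave 0.0818 for H3K4me3 on X, 0.116 for H3K27me3 on X, 0.0818 for H3K27me3 at gene ends, 0.950 for H3K27me3 in gene bodies. Location with the replicate number as a block gave 0.109 for H3K4me3 on X, 0.10 for H3K9me3 at gene ends, 0.050 for H4K20me1 at gene ends, 0.050 for H3K36me1 at gene ends, 0.0667 for RNA polymerase II at gene ends. Location without the CeHR reversion libraries gave 0.0623 for H3K4me3 on X, 0.171 for H3K9me3 at gene ends, 0.0381 for H4K20me1 on X, 0.0381 for H4K20me1 on arms, 0.0508 for H3K36me1 on X, 0.0623 for H3K36me1 at gene ends, 0.0952 for RNA polymerase II at gene ends. It gave 0.0508 for RNA polymerase II in gene bodies, 0.0508 for H3K27me3 in gene bodies. Location at equal list length gave 0.0783 for H3K9me3 at gene ends, 0.0310 for H3K9me3 in gene bodies, 0.0181 for H4K20me1 on X, 0.0127 for H4K20me1 on arms, 0.897 for H4K20me1 at gene ends, 0.0127 for H4K20me1 in gene bodies, 0.897 for H3K36me1 on X. It gave 0.103 for H3K36me1 at gene ends, 0.599 for RNA polymerase II on X, 0.897 for RNA polymerase II at gene ends, 0.0739 for RNA polymerase II in gene bodies, 0.0181 for H3K27me3 on arms. Location within 1000 bp of a gene end gave 0.105 for H4K20me1 at gene ends. Location with antibody-specific summits only gave 0.0503 for RNA polymerase II in gene bodies. Location with the outer 0.25 of each autosome at either end as arms gave 0.0254 for H3K27me3 on arms.

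Replicate overlap, as adjusted p of one-sided exact permutation tests. H3K4me3 had 0.0667 with the replicate number as a block. RNA polymerase II had 0.0519 at equal list length. Without the CeHR reversion libraries both had 0.0571.

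Changed genes, gained and lost together. Changed genes with only peaks scoring above their list's median gave 48 for H3K4me3 P0 to F1 CeHR, 223 for H3K4me3 F1 CeHR to reversion, 458 for H3K4me3 F1 S-Medium to reversion, 269 for H3K9me3 P0 to F1 CeHR, 260 for H3K9me3 P0 to F1 S-Medium, 452 for H3K9me3 F1 CeHR to reversion, 47 for H3K9me3 F1 S-Medium to reversion. It gave 285 for H4K20me1 P0 to F1 CeHR, 589 for H4K20me1 P0 to F1 S-Medium, 598 for H4K20me1 F1 CeHR to reversion, 129 for H4K20me1 F1 S-Medium to reversion, 230 for H3K36me1 P0 to F1 CeHR, 529 for H3K36me1 P0 to F1 S-Medium, 666 for H3K36me1 F1 CeHR to reversion. There were also 76 for H3K36me1 F1 S-Medium to reversion, 25 for RNA polymerase II P0 to F1 CeHR, 337 for RNA polymerase II P0 to F1 S-Medium, 95 for RNA polymerase II F1 CeHR to reversion, 340 for H3K27me3 P0 to F1 CeHR, 751 for H3K27me3 P0 to F1 S-Medium, 726 for H3K27me3 F1 CeHR to reversion. There were also 290 for H3K27me3 F1 S-Medium to reversion. Changed genes at equal list length gave 33 for H3K4me3 P0 to F1 CeHR, 84 for H3K4me3 F1 CeHR to reversion, 170 for H3K4me3 F1 S-Medium to reversion, 106 for H3K9me3 P0 to F1 CeHR, 167 for H3K9me3 P0 to F1 S-Medium, 76 for H3K9me3 F1 CeHR to reversion, 32 for H3K9me3 F1 S-Medium to reversion. It gave 66 for H4K20me1 P0 to F1 CeHR, 71 for H4K20me1 P0 to F1 S-Medium, 64 for H4K20me1 F1 CeHR to reversion, 3 for H4K20me1 F1 S-Medium to reversion, 108 for H3K36me1 P0 to F1 CeHR, 177 for H3K36me1 P0 to F1 S-Medium, 282 for H3K36me1 F1 CeHR to reversion. There were also 8 for H3K36me1 F1 S-Medium to reversion, 45 for RNA polymerase II P0 to F1 CeHR, 39 for RNA polymerase II P0 to F1 S-Medium, 118 for RNA polymerase II F1 CeHR to reversion, 34 for RNA polymerase II F1 S-Medium to reversion, 541 for H3K27me3 F1 CeHR to reversion, 460 for H3K27me3 F1 S-Medium to reversion. Changed genes with gene ends only gave 33 for H3K4me3 P0 to F1 CeHR, 68 for H3K4me3 P0 to F1 S-Medium, 107 for H3K4me3 F1 CeHR to reversion, 277 for H3K4me3 F1 S-Medium to reversion, 273 for H3K9me3 P0 to F1 CeHR, 257 for H3K9me3 P0 to F1 S-Medium, 208 for H3K9me3 F1 CeHR to reversion. It gave 195 for H4K20me1 P0 to F1 CeHR, 442 for H4K20me1 P0 to F1 S-Medium, 274 for H4K20me1 F1 CeHR to reversion, 127 for H4K20me1 F1 S-Medium to reversion, 171 for H3K36me1 P0 to F1 CeHR, 408 for H3K36me1 P0 to F1 S-Medium, 346 for H3K36me1 F1 CeHR to reversion. There were also 50 for RNA polymerase II P0 to F1 CeHR, 287 for RNA polymerase II P0 to F1 S-Medium, 113 for RNA polymerase II F1 CeHR to reversion. Changed genes with antibody-specific summits only gave 41 for H3K4me3 P0 to F1 CeHR, 88 for H3K4me3 P0 to F1 S-Medium, 343 for H3K4me3 F1 S-Medium to reversion, 197 for H3K9me3 F1 CeHR to reversion, 158 for H4K20me1 P0 to F1 CeHR, 584 for H4K20me1 P0 to F1 S-Medium, 147 for H4K20me1 F1 CeHR to reversion. It gave 501 for H4K20me1 F1 S-Medium to reversion, 523 for H3K36me1 P0 to F1 S-Medium, 342 for H3K36me1 F1 CeHR to reversion, 378 for H3K36me1 F1 S-Medium to reversion, 283 for RNA polymerase II P0 to F1 CeHR, 342 for RNA polymerase II F1 S-Medium to reversion. Changed genes with absence required within 2000 bp gave 47 for H3K9me3 F1 S-Medium to reversion, 63 for H3K36me1 F1 S-Medium to reversion, 70 for RNA polymerase II F1 S-Medium to reversion, 492 for H3K27me3 P0 to F1 CeHR, 724 for H3K27me3 P0 to F1 S-Medium, 410 for H3K27me3 F1 S-Medium to reversion. Changed genes with a common score threshold gave 737 for H3K27me3 F1 CeHR to reversion, 306 for H3K27me3 F1 S-Medium to reversion. The larger of the gained and lost counts turned as follows, with the main counts in brackets. The counts with only peaks scoring above their list's median were 21 and 26 for H3K9me3 F1 S-Medium to reversion (38 and 37). The counts with a common score threshold were 329 and 389 for H3K27me3 P0 to F1 CeHR (384 and 362), 194 lost of 306 changed for H3K27me3 F1 S-Medium to reversion (556 and 195). The counts at equal list length were 76 and 94 for H3K4me3 F1 S-Medium to reversion (763 and 38), 60 and 46 for H3K9me3 P0 to F1 CeHR (217 and 391), 97 and 70 for H3K9me3 P0 to F1 S-Medium (222 and 320), 14 and 52 for H4K20me1 P0 to F1 CeHR (464 and 26). Also 16 and 55 for H4K20me1 P0 to F1 S-Medium (1020 and 35), 47 and 17 for H4K20me1 F1 CeHR to reversion (9 and 1043), 1 and 7 for H3K36me1 F1 S-Medium to reversion (78 and 37), 23 and 22 for RNA polymerase II P0 to F1 CeHR (28 and 48). Also 361 and 377 for H3K27me3 P0 to F1 CeHR (384 and 362). For H3K9me3 F1 S-Medium to reversion (38 and 37), the counts were 25 and 26 with gene ends only. With 1000 bp around genes they were 41 and 50. The counts with antibody-specific summits only were 372 and 54 for H3K4me3 F1 CeHR to reversion (17 and 349), 23 and 44 for H3K9me3 F1 S-Medium to reversion (38 and 37), 78 and 80 for H4K20me1 P0 to F1 CeHR (464 and 26), 274 lost of 378 changed for H3K36me1 F1 S-Medium to reversion (78 and 37). Also 268 and 78 for RNA polymerase II F1 CeHR to reversion (32 and 224), 90 and 252 for RNA polymerase II F1 S-Medium to reversion (64 and 47).

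Occupancy after reversion, as percentage points of genes gained minus genes lost in F1. Persistence with 1000 bp around genes gave −24.5 for H3K4me3 F1 CeHR, 66.7 for RNA polymerase II F1 S-Medium. Persistence with antibody-specific summits only gave −29.3 for H3K4me3 F1 CeHR, 1.04 for H3K9me3 F1 CeHR, 1.96 for H4K20me1 F1 S-Medium, 18.4 for RNA polymerase II F1 CeHR, 17 for RNA polymerase II F1 S-Medium. Persistence with only peaks scoring above their list's median gave −36.5 for H3K4me3 F1 S-Medium, 0 for RNA polymerase II F1 CeHR, −6.86 for H3K27me3 F1 CeHR. Persistence at equal list length gave −25.6 for H3K4me3 F1 S-Medium, −17.3 for H4K20me1 F1 CeHR, 61.1 for RNA polymerase II F1 S-Medium, 12.1 for H3K27me3 F1 CeHR. Persistence with gene ends only gave 19 for H3K4me3 F1 S-Medium, 0.0742 for H3K9me3 F1 CeHR, 0 for H4K20me1 F1 CeHR, 0 for H3K36me1 F1 CeHR, −8.43 for H3K27me3 F1 CeHR.

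Genes changed in both media. Shared change with gene ends only gave 3 for H3K4me3, 139 for H3K9me3, 137 for H4K20me1, 115 for H3K36me1, 10 for RNA polymerase II. Shared change with only peaks scoring above their list's median gave 88 for H3K9me3, 243 for H4K20me1, 169 for H3K36me1, 5 for RNA polymerase II. Shared change at equal list length gave 45 for H3K9me3, 63 for H4K20me1, 89 for H3K36me1, 11 for RNA polymerase II. Odds ratio for H3K4me3 and RNA polymerase II at the same genes. Co-change with only peaks scoring above their list's median gave 127 for P0 to F1 CeHR gained. Co-change at equal list length gave 14.2 for P0 to F1 S-Medium lost. Co-change with 1000 bp around genes gave 42.6 for P0 to F1 CeHR gained. Genes under an unadjusted p of 0.05 between liquid and agar, in Fisher's exact test. Liquid against agar at equal list length gave 4 for H3K4me3, 5 for H3K9me3, 1 for H4K20me1, 5 for H3K36me1, 12 for RNA polymerase II. Liquid against agar with gene ends only gave 2 for H3K4me3, 13 for H3K9me3, 33 for H4K20me1, 16 for H3K36me1. Liquid against agar with 1000 bp around genes gave 3 for H3K4me3, 102 for H4K20me1, 45 for H3K36me1. Liquid against agar with only peaks scoring above their list's median gave 13 for H3K9me3, 17 for H3K36me1, 1 for RNA polymerase II, 23 for H3K27me3.

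Gene lists past the threshold in limma. Lists with only peaks scoring above their list's median gave 0 for H3K4me3, 13 for H3K9me3, 71 for H3K36me1, 7 for RNA polymerase II, 9 for H3K27me3. Lists with a common score threshold gave 0 for H3K4me3, 50 for H3K27me3. Lists at equal list length gave 0 for H3K4me3, 17 for H3K9me3, 131 for H4K20me1, 3 for RNA polymerase II. Lists with 1000 bp around genes gave 0 for H3K4me3, 1 for H3K9me3. Lists with antibody-specific summits only gave 1 for H3K4me3, 17 for H4K20me1, 9 for H3K36me1. For H3K4me3, leaving out the nspc genes gave 0 and the replicate number as a block 3. Lists without the CeHR reversion libraries gave 0 for H3K4me3, 11 for H4K20me1, 15 for H3K36me1, 7 for RNA polymerase II. Lists with at least 2 expected per library gave 0 for H3K4me3, 13 for H4K20me1, 11 for H3K36me1. Lists with gene ends only gave 26 for H3K9me3, 151 for H4K20me1, 91 for H3K36me1, 11 for RNA polymerase II. Where no list passed for H3K4me3 or H3K9me3, 44 and 43 had an unadjusted p under 0.05 in the main analysis. Regions past the threshold in limma. Regions with only peaks scoring above their list's median gave 0 for H3K4me3, 8 for H3K9me3, 95 for H4K20me1, 39 for RNA polymerase II. Regions at equal list length gave 0 for H3K4me3, 0 for H3K9me3, 127 for H3K36me1, 0 for RNA polymerase II. Regions with the replicate number as a block gave 0 for H3K4me3, 53 for H4K20me1. Regions without the CeHR reversion libraries gave 7 for H3K4me3, 12 for H3K9me3, 157 for H4K20me1, 128 for H3K36me1, 0 for RNA polymerase II. Regions with 250 kb regions gave 0 for H3K4me3, 0 for H3K9me3, 212 for H4K20me1, 448 for H3K36me1, 333 for H3K27me3. Regions with 1000 kb regions gave 5 for H3K4me3, 0 for H3K9me3, 120 for H3K36me1. Regions with at least 2 expected per library gave 0 for H3K4me3, 0 for H4K20me1, 144 for H3K36me1. Regions with no minimum per region gave 18 for H3K9me3. Regions with 1 added to counts gave 10 for H3K9me3, 72 for H4K20me1. Regions with a common score threshold gave 113 for H4K20me1, 66 for H3K27me3. Where no region passed for H3K4me3, H3K9me3, H4K20me1 or RNA polymerase II, 177, 218, 293 and 350 had an unadjusted p under 0.05 in the main analysis.

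Lists and regions followed by name, as log2 change, where the direction turned. With only peaks scoring above their list's median: 0.10 for collagens of the cuticle H3K27me3 in F1 CeHR against P0, 0.20 for cytosolic ribosomal proteins H3K27me3 in F1 S-Medium against P0, 0.19 for vitamin B12, methionine and propionate metabolism H3K27me3 in F1 S-Medium against P0, −0.02 for hypodermis and seam markers H3K27me3 in S-Medium reversion against F1 S-Medium, 0.36 for collagens of the cuticle H4K20me1 in F1 CeHR against F1 S-Medium, 0.32 for X at 6000001–6500000 H3K27me3 in F1 CeHR against P0, −0.26 for V at 17000001–17500000 H3K27me3 in F1 S-Medium against P0, −0.46 for X at 6000001–6500000 H3K27me3 in CeHR reversion against F1 CeHR, 0.25 for V at 17000001–17500000 H3K27me3 in F1 CeHR against F1 S-Medium. With gene ends only: −0.04 for dosage compensation H3K27me3 in F1 CeHR against P0, 0.38 for mitochondrial ribosomal proteins H3K27me3 in F1 S-Medium against P0, −0.35 for ion channels H4K20me1 in F1 S-Medium against P0, 0.61 for chemosensory receptor families H4K20me1 in CeHR reversion against F1 CeHR. With the nspc genes left out: −0.13 for osmotic stress and water or glycerol transport H3K27me3 in CeHR reversion against F1 CeHR, 0.42 for osmotic stress and water or glycerol transport H3K27me3 in F1 CeHR against F1 S-Medium. At equal list length: 0.02 for collagens of the cuticle H4K20me1 in F1 CeHR against F1 S-Medium. Of the other values of these lists and regions, 366 stayed and 93 ended, and with single libraries left out 563 stayed and 57 ended. Of the 48 genes named by rank, 21 kept their change with absence required within 2000 bp and 12 of 40 with antibody-specific summits only. All 48 kept it with a common score threshold, 32 at equal list length and 26 with 1000 bp around genes. Among peaks scoring above their list's median 43 kept it, with gene ends only 35, and none turned.

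With each library left out in turn, the remaining one is assumed to vary like the other groups. Across these fits 417 values stayed, 114 counts moved, 32 ended and 13 came to pass. Adjusted p for peak number, in exact permutation tests: H3K4me3 0.0470 (without P0 replicate 2) to 0.350 (without S-Medium reversion replicate 2), H3K9me3 0.0175 (without S-Medium reversion replicate 1) to 0.138 (without F1 S-Medium replicate 1), RNA polymerase II 0.00847 (without F1 CeHR replicate 1) to 0.0603 (without CeHR reversion replicate 1). For location, in the same exact tests: H3K27me3 on arms 0.0254 (without F1 CeHR replicate 1) to 0.0947 (without P0 replicate 1), H3K36me1 on X 0.0102 (without CeHR reversion replicate 2) to 0.211 (without F1 S-Medium replicate 2), H3K36me1 on arms 0.0226 (without CeHR reversion replicate 2) to 0.990 (without F1 CeHR replicate 2). H3K4me3 in gene bodies 0.0423 (without P0 replicate 2) to 0.643 (without S-Medium reversion replicate 1), H3K4me3 on X 0.0127 (without F1 S-Medium replicate 1) to 0.0940 (without P0 replicate 1), H3K4me3 on arms 0.0423 (without F1 CeHR replicate 1) to 0.152 (without P0 replicate 1). H3K9me3 at gene ends 0.0218 (without S-Medium reversion replicate 2) to 0.0571 (without F1 CeHR replicate 2), H4K20me1 on arms 0.00847 (without CeHR reversion replicate 2) to 0.987 (without P0 replicate 2), H4K20me1 at gene ends 0.0127 (without F1 S-Medium replicate 1) to 0.0533 (without S-Medium reversion replicate 2). RNA polymerase II on arms 0.0286 (without F1 CeHR replicate 1) to 0.565 (without P0 replicate 1), RNA polymerase II at gene ends 0.00847 (without P0 replicate 2) to 0.0577 (without CeHR reversion replicate 1). For replicate overlap: H3K4me3 0.00317 (without P0 replicate 2) to 0.189 (without S-Medium reversion replicate 2).

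Changed genes with 1 library left out: H3K27me3 F1 CeHR to reversion 1503 (without F1 CeHR replicate 2) to 2301 (without CeHR reversion replicate 1), H3K27me3 F1 S-Medium to reversion 1165 (without F1 S-Medium replicate 2) to 1520 (without S-Medium reversion replicate 1), H3K27me3 P0 to F1 CeHR 1032 (without P0 replicate 2) to 1399 (without P0 replicate 1). H3K27me3 P0 to F1 S-Medium 1678 (without P0 replicate 1) to 1832 (without F1 S-Medium replicate 2), H3K36me1 F1 S-Medium to reversion 235 (without S-Medium reversion replicate 2) to 368 (without F1 S-Medium replicate 1), H3K36me1 P0 to F1 CeHR 470 (without P0 replicate 1) to 706 (without P0 replicate 2). H3K36me1 P0 to F1 S-Medium 1006 (without P0 replicate 1) to 1428 (without F1 S-Medium replicate 2), H3K4me3 F1 CeHR to reversion 472 (without CeHR reversion replicate 1) to 730 (without F1 CeHR replicate 1), H3K4me3 F1 S-Medium to reversion 893 (without F1 S-Medium replicate 2) to 1265 (without F1 S-Medium replicate 1). H3K4me3 P0 to F1 CeHR 154 (without F1 CeHR replicate 2) to 878 (without P0 replicate 2), H3K4me3 P0 to F1 S-Medium 244 (without F1 S-Medium replicate 1) to 583 (without P0 replicate 1), H3K9me3 F1 S-Medium to reversion 187 (without F1 S-Medium replicate 1) to 543 (without S-Medium reversion replicate 2). H3K9me3 P0 to F1 S-Medium 700 (without P0 replicate 2) to 821 (without P0 replicate 1), H4K20me1 F1 S-Medium to reversion 375 (without S-Medium reversion replicate 1) to 1280 (without F1 S-Medium replicate 1), H4K20me1 P0 to F1 S-Medium 1152 (without P0 replicate 2) to 1985 (without F1 S-Medium replicate 1). RNA polymerase II F1 CeHR to reversion 297 (without CeHR reversion replicate 2) to 816 (without F1 CeHR replicate 2), RNA polymerase II F1 S-Medium to reversion 339 (without F1 S-Medium replicate 2) to 521 (without F1 S-Medium replicate 1), RNA polymerase II P0 to F1 CeHR 142 (without P0 replicate 1) to 425 (without F1 CeHR replicate 1). RNA polymerase II P0 to F1 S-Medium 772 (without P0 replicate 2) to 1306 (without F1 S-Medium replicate 1). Requiring 1 library in place of 2 admits more genes by construction. Lists past the threshold in limma: H3K36me1 23 (without F1 CeHR replicate 2) to 67 (without CeHR reversion replicate 2), H3K4me3 0 (without F1 S-Medium replicate 1) to 56 (without P0 replicate 2), H3K9me3 0 (without P0 replicate 1) to 4 (without CeHR reversion replicate 1). H4K20me1 24 (without F1 CeHR replicate 1) to 110 (without F1 S-Medium replicate 1), RNA polymerase II 8 (without S-Medium reversion replicate 1) to 60 (without F1 CeHR replicate 1). Regions past the threshold in limma: H3K27me3 121 (without F1 S-Medium replicate 1) to 199 (without CeHR reversion replicate 1), H3K36me1 196 (without F1 CeHR replicate 2) to 563 (without CeHR reversion replicate 2), H3K4me3 0 (without F1 CeHR replicate 1) to 218 (without P0 replicate 2). H3K9me3 0 (without P0 replicate 1) to 431 (without CeHR reversion replicate 1), H4K20me1 5 (without S-Medium reversion replicate 1) to 434 (without CeHR reversion replicate 1), RNA polymerase II 21 (without P0 replicate 2) to 233 (without F1 CeHR replicate 1).

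The shared replicate number is not stated to pair samples, and correlations of same-number residuals ranged from −0.284 to 0.395, so it served only as an alternative. As a block it changed no call on peak number and no count of lists by over 1.5 times except for H3K4me3. The sources used here give neither sequencing depth nor whether replicates were separate cultures, so each p measures the spread between samples, and differences in peak number cannot be told from differences in depth.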

Other observations

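The comparison across antibodies was a test written before the data were examined, and the grouping by S-Medium line was chosen after seeing the data. Summit lists of different antibodies resembled each other more within a condition than between conditions, by 0.116 in Jaccard index (permutation p = 1e-05, the smallest that 100000 permutations can give). By condition the index across antibodies was 0.613 in F1 CeHR, 0.611 in S-Medium reversion, 0.508 in F1 S-Medium, 0.436 in P0 and 0.200 in CeHR reversion. A component of the condition common to all antibodies, such as its extract or control library, fits this value, and a change of chromatin seen by all antibodies would give it as well.

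Splits of the 10 libraries into 4 and 6 gave as many genes as liquid against agar in 98 of 100 cases for H3K4me3, 57 for RNA polymerase II, 33 for H3K27me3, 30 for H3K9me3, 25 for H3K36me1 and 15 for H4K20me1, the real split included, so liquid culture did not stand out. The highest of the other splits drawn gave 363, 465, 547, 193, 307 and 604 genes in that order. The 4 libraries of the S-Medium line, F1 and reversion together, against all others gave 962 genes for H3K27me3, 794 for RNA polymerase II, 710 for H3K36me1 and 193 for H3K9me3, each the most of all 210 splits, but 576 for H4K20me1 (most 604) and 53 for H3K4me3 (most 363).

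H3K4me3 occupied 69.4 ± 3.93% of the nspc genes in S-Medium reversion and none in any other condition. All 18 nspc genes lie on X, in 3 clusters, and these libraries had the large X share given above. H4K20me1 also occupied nspc genes in the S-Medium line alone, 52.8 ± 27.5% in F1 and 30.6 ± 3.93% in reversion. Whether the X share accounts for this was not tested.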
